A study of Mus musculus with 30 samples.

How the data were processed

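RNA of pooled mouse embryonic tissue was measured on 30 arrays, 16 Affymetrix mRNA arrays and 14 Affymetrix miRNA arrays. Whether an mRNA and a miRNA array shared a pool, or both tissues came from the same embryos, is not stated. Per the labels, embryos were collected at embryonic day 9.5 with 19 to 21 somite pairs, tissue of one genotype from at least 5 litters was pooled, and 100 ng of total RNA entered the mRNA labelling. Groups were taken from the labels as tissue (aSHF or OFT-RV) by genotype (wild-type, Dgcr8 f/+ without Cre, or mutant, Mef2c-AHF-Cre with Dgcr8 f/f). Each had 4 arrays, or 3 for the OFT-RV miRNA groups.

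The array values are log2 values that the authors made with RMA in the R package oligo, per the submitters' processing notes, whose versions are not given in the sources used here. Array medians and distributions differed between the tissues and matched within each, so the values show each tissue to have been normalized on its own. For that reason wild-type tissues were not compared with each other, and differences in change between tissues are given with this limit. The authors' comparison tables hold, per the file headers, log2 changes, mean values, p-values and adjusted p-values, and the tool behind these p-values is not given in the sources used here. The authors' adjusted p-values for genes were computed over more probe sets than the tables list. A further 4 tables with 30 columns of values were not used here, because their column names match no sample label.

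Probe sets of the mRNA arrays carry numbers only, so names were taken from the authors' tables by matching mean value and change of each gene to a probe set within 1e-06. All 20889 listed genes were matched. Left out were 45 genes that share their probe set with another gene and 2 second listings of a symbol, which left 20842 genes, 321 of them miRNA genes and 19853 protein-coding. The mRNA arrays held 35556 probe sets. Of 36353 probe sets on the miRNA arrays, 3163 were named as mouse by the authors' tables, of which 1908 were mature miRNAs and 1255 precursors. There were 95 background probe sets, 22 spike-ins and 2006 small RNAs outside miRBase whose organism is not named. The gene table given as reference (GRCm38.p6) served only for names and for finding genes that span miRNA genes, and the build behind the authors' locations is not given in the sources used here.

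Mutant and wild-type arrays were compared within each tissue with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the only term. No paired term was used, since the replicate numbers are not stated to mark shared litters. The p-values were adjusted by Benjamini and Hochberg over all genes, or over mature miRNAs, and a gene passed at an adjusted p under 0.05 with no minimum change. Differences between the tissues' changes were tested in a fit of 4 groups. Dgcr8 was also tested by exact two-sided permutation of the arrays. For its difference between tissues both tissues were permuted at once, which tests no change in either tissue. Enrichment of miRNA genes used Fisher's exact test, and overlaps were set against the hypergeometric expectation. Both count miRNA genes of a cluster as independent draws, so their p-values are too small. SE is the moderated standard error of the change and SD the spread between pools.

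In total 19 gene lists and 14 miRNA lists were fixed in advance. The gene lists were miRNA machinery, host transcripts of miRNAs, second heart field progenitors, cardiomyocyte, smooth muscle, branchiomeric muscle, neural crest, endothelium and endocardium, pharyngeal endoderm and epithelium, neural, primitive erythroid, epicardium, p53 targets, cell cycle, extracellular matrix and mesenchymal transition, let-7 targets, miR-17 and miR-302 targets, retinoic acid, and BMP, Wnt and Notch response. The miRNA lists were muscle, miR-17-92 and its paralogs, let-7, miR-302, miR-367 and miR-290 clusters, epithelial, erythroid, endothelial, neural, Dlk1-Dio3 locus, miR-199 and miR-214, miR-15 and miR-16, miR-130 and miR-301, miR-143 and miR-145, and Microprocessor-independent. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of one comparison. Members were also adjusted over the list alone. A p in parentheses after a list is its adjusted p by camera at the preset correlation.

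Genes are named by a rule. Dgcr8 comes first, then up to 12 called genes with the largest rise and 12 with the largest fall among those whose groups do not overlap, and for miRNAs 10 in each direction. Where none was called the 6 with the smallest p in each direction are given. For differences between tissues the 10 largest in each direction are given, and from each list up to 4 members with the smallest p. Other names are marked as chosen after their values were seen.

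Each miRNA gene was joined to its mature miRNAs by the authors' locations, and the brightest one with a mean above 3 in the tissue was used, with 100000 permutations for each correlation. A mature miRNA of several loci was first assigned to the locus whose gene had the highest change in that tissue. This choice used the gene changes under test, so it can affect the correlations and the split by call. Random sets of probe sets matched on wild-type level were drawn 10000 times from the 50 nearest neighbours of each member, and intervals of rank correlations came from 2000 bootstrap draws. Other divisions of the same arrays into groups were counted, up to 100 per comparison, for all genes and, chosen after seeing the data, for miRNA genes. An array was taken to stand apart from its group of 4 when its gap to the next value exceeded 0.829 of the group's range.

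Each comparison was tested on simulated data made from the deposited values, with 200 genes or miRNAs changed. Noise was drawn independently per gene, so structure that genes share across arrays was not simulated. At a log2 change of 1 the share recovered was 100% for genes in both tissues, 95.5% for aSHF miRNAs, 92.5% for OFT-RV miRNAs, and 79.1% for miRNAs that differed between tissues. At a change of 0.5 it was 91.0% and 85.1% for genes and 70.1% and 64.2% for miRNAs, in aSHF and OFT-RV. For differences between tissues it was then 82.1% for genes and 41.8% for miRNAs. The false share of calls ran from 2.3% for OFT-RV miRNAs to 8.4% for aSHF miRNAs.

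Alternatives planned in advance were a second quantile normalization, centring on array medians, leaving out dim probe sets, an intensity trend with a robust prior, array weights, a replicate block, all arrays in one fit, a minimum change of 1 on the log2 scale, all mouse probe sets, an estimated correlation and fry for gene lists, and leaving out each array. Chosen after seeing the data were a fit of all probe sets, centring on small RNAs outside miRBase or on spike-ins, a filter on background probe sets, and the estimated correlation, fry, block and filter for miRNA lists, and leaving out each array for all lists. A test of seed matches in transcripts was not run, since no transcript sequences were used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.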

Results

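Expression was measured on 16 mRNA arrays and 14 miRNA arrays of mouse embryos at embryonic day 9.5, with 19 to 21 somite pairs. Both the anterior second heart field (aSHF), which holds progenitors behind the heart tube, and the outflow tract with the right ventricle (OFT-RV), part of the tube itself, had been dissected. Mutant embryos carried Mef2c-AHF-Cre, which is active in the anterior second heart field and its descendants, and 2 floxed alleles of Dgcr8. Wild-type embryos carried 1 floxed allele and no Cre. Each array held a pool of one genotype, drawn from at least 5 litters, and arrays of one group are labelled as biological replicates. Whether pools or embryos were shared between the 2 array types or the 2 tissues is not stated. Each group had 4 arrays, except for the OFT-RV miRNA groups, which had 3 arrays each, and these small numbers limit the precision.

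Dgcr8, the targeted gene, encodes the RNA-binding partner of Drosha in the Microprocessor, the enzyme that cuts hairpins out of primary miRNA transcripts. In aSHF its log2 value was 10.34 ± 0.06 (SD, n = 4) in wild-type pools and 10.22 ± 0.05 (SD, n = 4) in mutant pools. The aSHF values overlapped, with a change of -0.12 (SE 0.05). By limma its unadjusted p was 0.0258 and its adjusted p over all genes 0.978, and an exact two-sided permutation test gave p = 0.0571. In OFT-RV Dgcr8 fell by 0.41 on the log2 scale (SE 0.06, adjusted p = 0.00753), from 8.11 ± 0.11 (SD, n = 4) to 7.70 ± 0.07 (SD, n = 4). The OFT-RV groups did not overlap, and the exact permutation p was 0.0286, the smallest that 4 arrays against 4 allow. The 2 tissues' Dgcr8 changes differed by -0.29 (SE 0.08), which did not pass with an adjusted p of 0.409 by limma. Where on the gene the Dgcr8 probe set lies relative to the deleted part is not in the files used here.

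In aSHF mutants, genes that encode miRNAs were higher than in wild-type pools. Mir19b-1 rose by 2.13 on the log2 scale (SE 0.11, n = 4 per group, adjusted p = 1.42e-05), a 4.37-fold change. Of its neighbours in the miR-17-92 cluster, a polycistron expressed in proliferating progenitors, Mir20a rose by 1.69 (SE 0.11), Mir17 by 1.47 (SE 0.08) and Mir92-1 by 1.41 (SE 0.07). The other two, Mir18 at 0.89 (SE 0.16, adjusted p = 0.0809) and Mir19a at 0.37 (SE 0.21, adjusted p = 0.978), did not pass in aSHF. Mir301 rose by 1.99 (SE 0.14), and Mir145a, from a locus known in smooth muscle, by 1.24 (SE 0.15). Mir136, Mir369 and Mir376b, from the imprinted Dlk1-Dio3 locus, rose by 1.80 (SE 0.25), 1.55 (SE 0.22) and 1.44 (SE 0.21), and Mirg, a long host transcript of the same locus, by 1.49 (SE 0.12). Mir181a-1 rose by 1.61 (SE 0.25), and its neighbour Mir181b-1 rose from 7.46 ± 0.13 to 8.86 ± 0.45 (SD).

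Of 20842 genes tested in aSHF by limma, 37 passed and all of these rose. They comprised 36 of the 321 miRNA genes (Fisher's exact test, two-sided, p = 2.77e-65) and Mirg. Of the 36, 11 were of the Dlk1-Dio3 locus, and genes of a cluster are not independent draws, so this p is too small. None of the 19853 protein-coding genes passed in aSHF. At an unadjusted p under 0.05 there were 555 genes, against 1042.1 that chance would give. This count was 1425 without wild-type replicate 2 and 1910 without mutant replicate 1, and 379 to 468 without any other array. With a replicate block it was 1721 and with array weights 3493, so its place below chance depended on arrays and fit. The wild-type and mutant arrays did not overlap for any of the 37 genes. Chance gives this separation to 2.86% of unselected genes, but these were picked by p on the same arrays, so it adds no support. Of all 321 miRNA genes, called or not, 260 were higher in aSHF mutants (median 0.085). The count of 37 became 21 without wild-type replicate 3, 19 without wild-type replicate 4, and 11 when dim probe sets were left out. Mir136, Mir181a-1, Mir369, Mir376b, Mir181b-1 and Mir145a each lost their call without wild-type replicate 4, and all but Mir145a also without others of wild-type replicates 1, 2 and 3 or mutant replicates 1, 3 and 4, while 1 other division of the 8 arrays into 4 and 4 called 1285 genes, none of them among the 37.

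**Figure D1:**
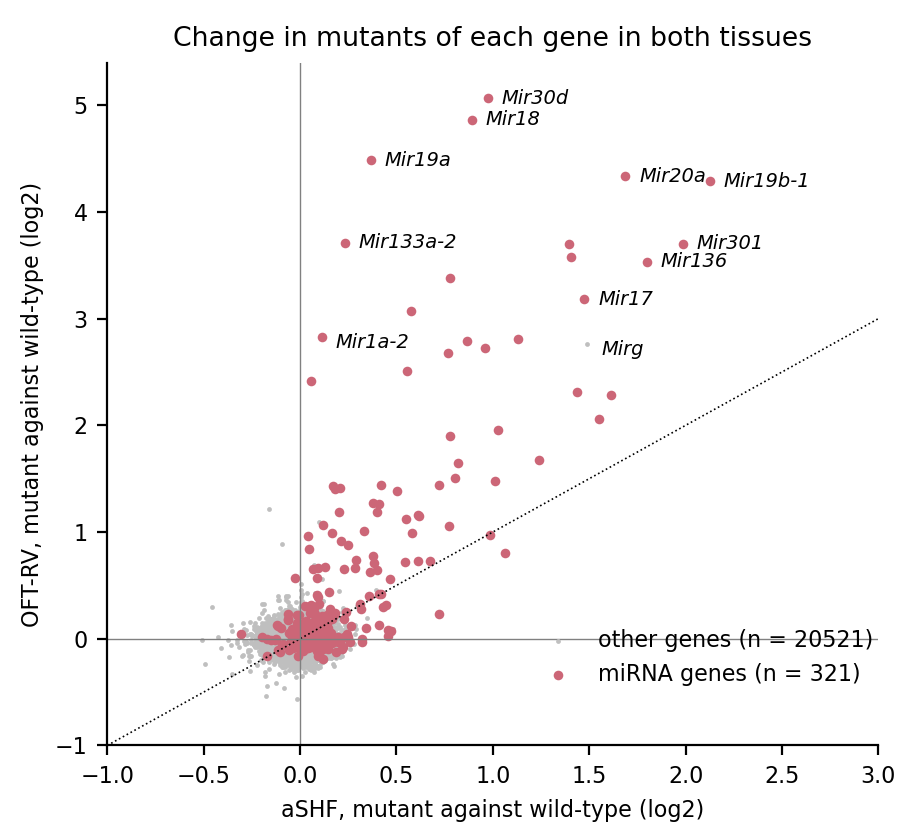
Change in mutants (log2) of each of 20842 genes in aSHF (horizontal axis) and OFT-RV (vertical axis), with 321 miRNA genes in red, other genes in grey and a dotted line where both changes are equal. Of the 321 miRNA genes 176 lie above the line, and of the 77 that passed in either tissue, 75 of them in OFT-RV, 71 do.

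Gene lists fixed in advance showed little change outside miRNA genes in aSHF. Among 6 measured host transcripts of miRNAs, Mirg rose and the other 5 did not pass, including Dnm3os, host of the miR-199 and miR-214 locus, at -0.17 (SE 0.07). The list's median was -0.015, its mean 0.20, and its test upward (camera, adjusted p = 0.822). None of 13 primitive erythroid genes passed, but all 13 were higher (median 0.12), among them Epb42 of the red cell membrane at 0.22 (SE 0.09) and Gata1, the erythroid transcription factor, at 0.19 (SE 0.10). Primitive erythroid genes were the only list in aSHF that passed against other genes (camera, adjusted p = 0.00418), with an adjusted p = 0.840 with an estimated correlation. They no longer passed without wild-type replicate 2 (adjusted p = 0.646), mutant replicate 1 (0.0989) or mutant replicate 4 (0.328).

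Progenitor and lineage markers did not pass in aSHF. Of 23 second heart field progenitor genes 14 were higher (adjusted p = 0.374), with Fgf8, a growth factor of the outflow tract's progenitors, at 0.29 (SE 0.08) and Tbx1 at 0.11 (SE 0.06). Of 24 cardiomyocyte genes 16 were lower (adjusted p = 0.374), with the myosin gene Myh6 at -0.20 (SE 0.14). Of 12 smooth muscle genes 6 were lower (0.374), with Tagln at -0.14 (SE 0.07). Of 10 branchiomeric muscle genes 9 were higher (0.374), and of 18 neural crest genes 11 were higher (0.819). Of 14 endothelial and endocardial genes 9 were lower (0.819), their median and test being downward and their mean 0.0032. Of 18 pharyngeal endoderm and epithelium genes 13 were higher (0.822), although Foxa2, an endoderm regulator, was at -0.21 (SE 0.07). Of 13 neural genes 8 were lower (0.241), with the neuronal gene Stmn2 at -0.36 (SE 0.15). Of 9 epicardium and proepicardium genes 5 were higher (0.591), with Tbx18 at -0.28 (SE 0.08), a median of 0.0038, a mean of -0.011 and a downward test. Some of these lists passed on leaving out 1 array. Without mutant replicate 4 cardiomyocyte (adjusted p = 1.81e-09) and smooth muscle genes (0.0277) were lower. Progenitor genes were higher without wild-type replicate 3 (0.0382) or mutant replicate 2 (0.00979), and neural genes lower without either of these (0.00525 and 0.0181) or wild-type replicate 1 (0.0216).

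Among signalling and proliferation lists in aSHF, 8 of 15 miRNA machinery genes were lower (0.241), with Drosha at -0.08 (SE 0.05). Of 22 p53 targets 11 were lower (0.374) and of 24 cell cycle genes 13 were lower (0.374), with Top2a at -0.11 (SE 0.06). Of 19 extracellular matrix and mesenchymal transition genes 14 were lower (0.0515), with Lum at -0.16 (SE 0.06). Of 14 textbook targets of let-7 8 were higher (0.374), with Nr6a1, an orphan nuclear receptor, at 0.20 (SE 0.08). Of 17 textbook targets of miR-17 and miR-302 11 were lower (0.374). Of 14 retinoic acid genes 8 were higher (0.574), with the retinoic acid hydroxylase Cyp26b1 at 0.18 (SE 0.05). Of 19 BMP, Wnt and Notch response genes 11 were lower (0.374), with Sp5 at 0.22 (SE 0.08). Extracellular matrix genes passed without wild-type replicate 1 (adjusted p = 0.00535) or mutant replicate 4 (0.0187), and machinery genes without mutant replicate 4 (0.0260). Adjusted over the list alone, Mirg was the only member of these 19 lists that passed in aSHF.

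In OFT-RV mutants more miRNA genes passed than in aSHF. Mir30d rose by 5.07 on the log2 scale (SE 0.10, n = 4 per group, adjusted p = 7.37e-11), from 5.93 ± 0.14 (SD) to 10.99 ± 0.22 (SD), and its neighbour Mir30b by 3.38 (SE 0.16). Of the miR-17-92 cluster, Mir18 rose by 4.87 (SE 0.10), Mir19a by 4.49 (SE 0.11), Mir20a by 4.34 (SE 0.12), Mir19b-1 by 4.29 (SE 0.08), Mir92-1 by 3.58 (SE 0.10) and Mir17 by 3.18 (SE 0.10). Mir133a-2, of a pair of muscle miRNA loci, rose by 3.71 (SE 0.15), Mir181b-1 and Mir301 each by 3.70 (SE 0.13 and 0.12), and Mir136 by 3.54 (SE 0.11). Apart from Dgcr8, Tspan13, which encodes a tetraspanin, fell by 0.57 (SE 0.07, adjusted p = 0.00188), and Kcnn2, which encodes a calcium-activated potassium channel, fell by 0.31 (SE 0.05, adjusted p = 0.0234).

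Of 20842 genes tested in OFT-RV by limma, 93 passed, of which 90 rose and 3 fell. Of all 321 miRNA genes, called or not, 218 were higher (median 0.047), fewer than in aSHF. The 93 included 75 of the miRNA genes (Fisher's exact test, two-sided, p = 6.48e-122). Of the 75, 23 were of the Dlk1-Dio3 locus, and genes of a cluster are not independent draws, so this p is too small. The 93 also included 16 protein-coding genes, 13 of which rose. Without mutant replicate 1 there were 9, of which 7 rose, and without wild-type replicate 3 there were 13, of which 8 rose, while the highest count was 21 without wild-type replicate 1. Chosen after their values were seen, the largest protein-coding rises were those of 2610318N02Rik at 1.09 (SE 0.08), of Nanos3, an RNA-binding protein of germ cells, at 0.69 (SE 0.06), and of Prtg, a receptor of the early embryo, at 0.66 (SE 0.07). For all 93 genes the arrays of the 2 genotypes did not overlap, which chance gives 2.86% of unselected genes. These genes were picked by p on the same arrays, so the separation adds no support. The count at an unadjusted p under 0.05 was 1216, against 1042.1 that chance would give. It was 1852 without wild-type replicate 1, and 1028 to 1182 without any other array. Leaving out dim probe sets gave 46 genes, and Kcnn2 no longer passed without any one of wild-type replicates 1, 2 and 4 or mutant replicates 1, 2 and 3.

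**Figure D2:**
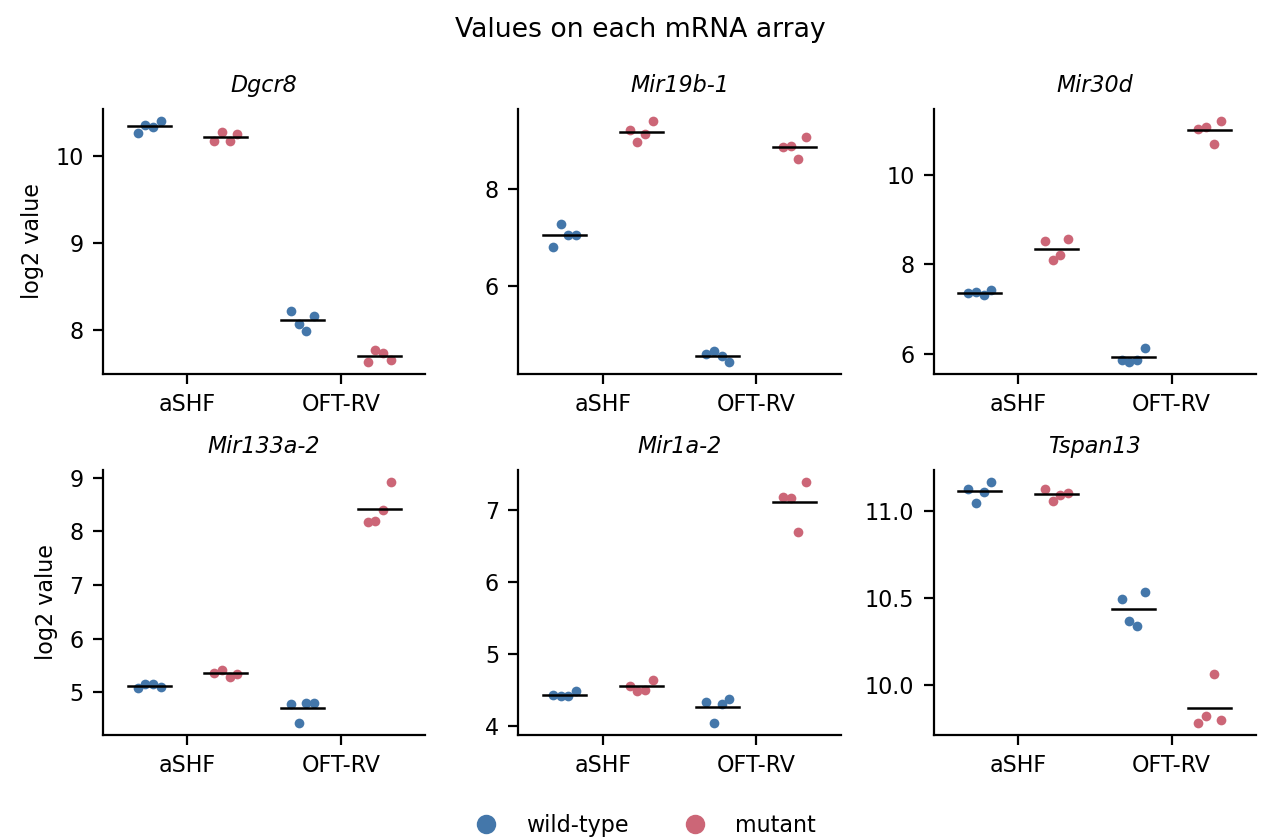
Log2 value of 6 genes on each of the 16 mRNA arrays (points), with the mean of each group of 4 (lines), wild-type in blue and mutant in red. Mir133a-2 lies near 5.12 and 5.35 in the 2 aSHF groups but at 4.71 and 8.42 in the OFT-RV groups, and tissues were normalized apart, so levels are compared within a tissue.

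Targets of let-7, a miRNA family that limits growth and pluripotency genes, were higher as a group in OFT-RV. Of 14 textbook targets 10 were higher (median 0.079), Nr6a1 rose by 0.44 (SE 0.05, adjusted p = 0.00121) and 13 did not pass. Adjusted over the list alone 3 rose, the others being the cyclin gene Ccnd1 at 0.26 (SE 0.06) and Arid3b at 0.16 (SE 0.05). The let-7 target list passed against other genes (camera, adjusted p = 3.61e-06), with an adjusted p = 0.0558 with an estimated correlation. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, gave an adjusted p of 0.0113. Of 17 textbook targets of miR-17 and miR-302 none passed and 10 were lower (adjusted p = 0.905), their median and mean being -0.011 and -0.015 and their test upward.

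Within the miRNA machinery, 10 of 15 genes were higher in OFT-RV, Dgcr8 alone fell and none rose (adjusted p = 0.0863). The list passed without wild-type replicate 1 (adjusted p = 0.00316), mutant replicate 2 (0.0251) or mutant replicate 3 (0.0394). Adjusted over the list alone, Dgcr8 fell and Tnrc6a, a scaffold of the silencing complex, rose at 0.32 (SE 0.06). Among the 6 host transcripts of miRNAs, Mirg rose by 2.76 (SE 0.13) and 5 did not pass, with Meg3 of the same locus at 0.055 (SE 0.06). The host transcripts passed as a list (adjusted p = 0.00128), with an adjusted p = 0.359 with an estimated correlation.

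Smooth muscle, erythroid and cell cycle genes were slightly higher in OFT-RV mutants, with no member past the test. Of 12 smooth muscle genes 10 were higher (adjusted p = 0.0172, and adjusted p = 0.584 with an estimated correlation), with Myocd, a cofactor of smooth muscle and heart genes, at 0.17 (SE 0.05) and Cald1 at 0.18 (SE 0.07). All 13 primitive erythroid genes were higher (adjusted p = 0.00128, and adjusted p = 0.584 with an estimated correlation), with a median of 0.077 and Epb42 at 0.29 (SE 0.12). Of 24 cell cycle genes 17 were higher (adjusted p = 0.0261, and adjusted p = 0.614 with an estimated correlation), with Ccne1 and Aurkb both at 0.14 (SE 0.05), and an adjusted p = 0.0923 with dim probe sets left out. Cell cycle genes no longer passed without wild-type replicate 2 (adjusted p = 0.396, median -0.00062), wild-type replicate 3 (0.221) or mutant replicate 1 (0.189). Nor did smooth muscle genes without wild-type replicate 3 (0.0842) or mutant replicate 1 (0.189), or erythroid genes without wild-type replicate 2 (0.116) or mutant replicate 3 (0.110).

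The other 12 lists did not pass in OFT-RV, and no member passed over all genes. Of 24 cardiomyocyte genes 13 were higher (0.686, median 0.00050 and mean 0.0053, with camera upward and fry downward), and Pln, a regulator of calcium uptake at -0.26 (SE 0.06), was the only one lower when adjusted over the list alone. Of 14 endothelial and endocardial genes 10 were lower (0.243), with the tight junction gene Cldn5 at -0.27 (SE 0.06) alone passing over the list. Of 23 second heart field progenitor genes 14 were lower (0.677), with Fgf8 at 0.095 (SE 0.05). Of 10 branchiomeric muscle genes 8 were lower (0.137), with Tcf21 at -0.24 (SE 0.10). Of 18 neural crest genes 14 were lower (0.157), with Twist1 at -0.29 (SE 0.08). Of 18 pharyngeal endoderm and epithelium genes 14 were lower (0.240), although Krt18 was at 0.30 (SE 0.10), and this list passed without wild-type replicate 4 (adjusted p = 0.0385) or mutant replicate 4 (0.0459).

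Of 13 neural genes 9 were lower in OFT-RV (0.729), with Nefl at -0.16 (SE 0.07). Of 9 epicardium and proepicardium genes 5 were higher (0.917, fry downward), with Sema3d at -0.18 (SE 0.07). Of 22 p53 targets 12 were higher (0.917), their median being 0.0055, their mean -0.0061 and their test upward. Of 14 retinoic acid genes 7 were lower (0.905), and of 19 BMP, Wnt and Notch response genes 14 were lower (0.161), with Id2 at 0.12 (SE 0.05). Of 19 extracellular matrix and mesenchymal transition genes 16 were higher (0.0624), with Lum at 1.21 (SE 0.82) and Snai1 at -0.21 (SE 0.07). That list's mean stood at 9.13 on mutant replicate 4 and at 8.37 on average over the other mutant arrays, and Lum was at 0.080 without that array. The list passed without wild-type replicate 4 (adjusted p = 0.0385), mutant replicate 2 (0.0340) or mutant replicate 3 (0.00685).

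The response of miRNA genes differed between the tissues. Mir30d changed by 4.09 more in OFT-RV than in aSHF (SE 0.15, n = 4 per group, adjusted p = 1.95e-11), Mir19a by 4.12 (SE 0.25) and Mir18 by 3.97 (SE 0.20). Some muscle miRNA genes were among them, while Mir208a and Mir499, chosen after their values were seen, passed in neither tissue. Mir133a-2 differed by 3.48 (SE 0.17), Mir1a-2 by 2.72 (SE 0.15) and Mir133a-1 by 2.36 (SE 0.10), and none of these passed in aSHF. Mir20a, Mir30b and Mir181b-1 differed by 2.65 (SE 0.18), 2.61 (SE 0.21) and 2.31 (SE 0.25), and Mir322 rose by 3.08 (SE 0.13) in OFT-RV against 0.58 (SE 0.06) in aSHF. Tspan13 changed by -0.55 relative to aSHF (SE 0.09, adjusted p = 0.00374) and Flywch2 by -0.35 (SE 0.07, adjusted p = 0.0386).

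In all 44 genes differed between tissues by limma, 42 with the higher change in OFT-RV and 2 with the lower. They comprised 34 miRNA genes (Fisher's exact test, two-sided, p = 8.67e-54, too small since genes of a cluster are not independent draws), 8 protein-coding genes and others including Mirg. The protein-coding ones other than Tspan13 and Flywch2 were 2610318N02Rik, Nanos3, Prtg, Nmt2, Acsl4 and Ppp6c, chosen after their values were seen. The tissues had been normalized apart, and the difference between 2 changes within tissues cancels a shift of one tissue's arrays but not a difference in scale. The 8 protein-coding genes were 5 without any one of aSHF wild-type replicates 1, 3 and 4, aSHF mutant replicates 3 and 4, OFT-RV wild-type replicate 4 and OFT-RV mutant replicates 1 and 2. The count of 44 became 21 without dim probe sets, and Flywch2 no longer passed in 15 of the 16 fits that left out 1 array, the fit without OFT-RV mutant replicate 3 being the exception.

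Most genes that rose in aSHF also rose in OFT-RV. Of the 37 genes that rose in aSHF and the 90 that rose in OFT-RV, 35 were shared, where independent draws would share 0.16 (exact hypergeometric p = 5.48e-84). Across the 321 miRNA genes the 2 tissues' changes had a Pearson r of 0.79 and a Spearman rho of 0.52, and within them 34 of the 36 and 75 that rose were shared, against 8.41 by chance (p = 1.27e-22). Across all genes r was 0.41 and rho -0.071, and across protein-coding genes r was -0.064 and rho -0.088. Genes are not independent replicates, so these correlations carry no p-value. For the same reason the hypergeometric p-values, which count genes of a cluster as separate draws, are too small. Among the 10421 genes above the median of mean level over both tissues' arrays, with the calls of the full fits, 18 rose in aSHF, 39 in OFT-RV and 18 in both.

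No mature miRNA passed in aSHF. Among those lower in mutant pools were miR-145a-5p, known from smooth muscle, at -0.50 (SE 0.09), miR-214-3p, known from mesenchyme, at -0.47 (SE 0.09), let-7e-5p at -0.69 (SE 0.13) and miR-99a-5p at -1.61 (SE 0.31, n = 4 per group). Also lower were miR-337-5p of the Dlk1-Dio3 locus at -0.66 (SE 0.12) and miR-483-5p at -0.85 (SE 0.17). The 6 highest-ranked of those that were higher, again without passing, were miR-7048-5p at 0.43 (SE 0.08), miR-7025-5p at 0.79 (SE 0.14), miR-598-5p at 0.33 (SE 0.08), miR-3083-5p at 0.38 (SE 0.10), miR-7647-3p at 1.18 (SE 0.32) and miR-292-5p at 0.62 (SE 0.17). By limma 0 of 1908 mature miRNAs passed, with a lowest adjusted p of 0.170 and 114 at an unadjusted p under 0.05. Centring the arrays on small RNAs outside miRBase, a choice made after seeing the data, gave 5 that passed, all lower, and leaving out mutant replicate 2 gave 2.

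As groups, aSHF miRNAs of 4 lists were lower than other miRNAs. Of 40 Dlk1-Dio3 miRNAs 35 were lower (median -0.17, adjusted p = 2.35e-07, and adjusted p = 0.136 with an estimated correlation), with miR-411-5p at -0.68 (SE 0.20) and miR-337-5p passing over the list alone. All 6 miRNAs of the miR-199 and miR-214 locus were lower (median -0.37, adjusted p = 0.00100, and adjusted p = 0.152 with an estimated correlation), with miR-214-3p passing over the list alone. All 4 of the miR-130 and miR-301 family were lower (median -0.26, adjusted p = 0.0263, and adjusted p = 0.152 with an estimated correlation), with miR-301a-3p at -1.12 (SE 0.54). Both measured miRNAs of the miR-143 and miR-145 locus were lower and passed over the list alone (median -0.59, adjusted p = 0.000354, and adjusted p = 0.0908 with an estimated correlation), miR-143-3p being at -0.69 (SE 0.20). The miR-130 and miR-301 family no longer passed without wild-type replicate 1 (adjusted p = 0.123), wild-type replicate 2 (0.0763) or mutant replicate 4 (0.149).

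The other 10 miRNA lists did not pass in aSHF. Of 13 miRNAs of the miR-17-92 and paralogous clusters 10 were lower (0.0909), with miR-17-5p at -0.13 (SE 0.08). Of 9 let-7 family miRNAs 6 were lower (0.0909), let-7e-5p alone passing over the list. Of 11 miRNAs of the miR-302, miR-367 and miR-290 clusters 8 were higher (0.130), with miR-293-3p at 0.21 (SE 0.11). Of 7 muscle miRNAs 4 were higher (0.676, median 0.032), with a mean of -0.080 and a downward test, miR-133a-3p being at -0.59 (SE 0.18). Of 4 erythroid miRNAs 3 were higher (0.0628), with miR-451a, a Drosha product that bypasses Dicer, at 0.29 (SE 0.22). Of 7 epithelial miRNAs 4 were higher (0.567), of 2 endothelial 1 was lower (0.873), and of 6 of the miR-15-16 family 3 were lower (0.681). Of 6 neural miRNAs 3 were lower (0.991), their median and mean being -0.014 and -0.021 and their test upward. Of 7 miRNAs made without the Microprocessor, such as mirtrons, 4 were higher (0.567, median 0.054). With arrays centred on small RNAs outside miRBase the medians of the muscle, epithelial, Microprocessor-independent and miR-302 lists turned negative, at -0.17, -0.13, -0.14 and -0.10. The let-7 and erythroid lists passed with that centring (adjusted p = 0.00444 and 0.00972), and let-7 also with dim probe sets left out (adjusted p = 0.0280), while the miR-130 and miR-301 family then had an adjusted p = 0.0724. On leaving out 1 array, miR-17-92 miRNAs passed without wild-type replicate 4 (adjusted p = 0.0494), mutant replicate 2 (0.0457) or mutant replicate 3 (0.0326), let-7 without mutant replicate 4 (0.0377), and erythroid without wild-type replicate 4 (0.00624) or mutant replicate 3 (0.0326).

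**Figure D3:**
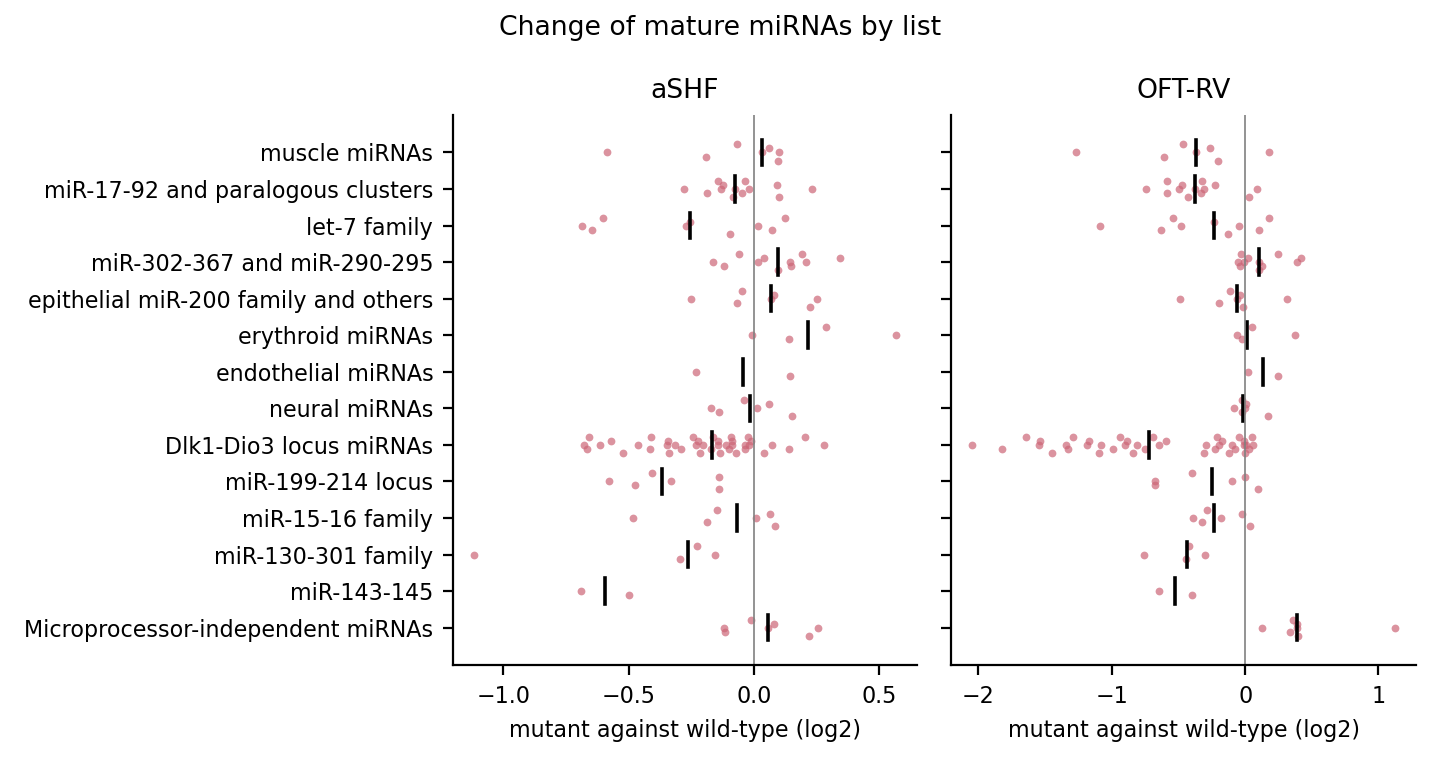
Change in mutants (log2) of each mature miRNA (points) in 14 lists, with list medians (bars), from 4 arrays per group in aSHF (left) and 3 in OFT-RV (right), on different scales. The Dlk1-Dio3 medians are -0.17 and -0.72, and the median of Microprocessor-independent miRNAs in OFT-RV is 0.39.

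In OFT-RV mutants 7 mature miRNAs fell. They belonged to the miR-378 family, known from mitochondrial metabolism, and to the Dlk1-Dio3 locus, except for miR-744-5p. In the family, miR-378b fell by 2.25 on the log2 scale (SE 0.20, n = 3 per group, adjusted p = 0.00787 by limma), miR-378c by 1.73 (SE 0.19) and miR-378a-3p by 1.37 (SE 0.18). At the Dlk1-Dio3 locus miR-543-3p fell by 1.82 (SE 0.11, adjusted p = 0.00140 by limma), miR-134-5p by 1.53 (SE 0.15) and miR-434-3p by 0.88 (SE 0.12). The last, miR-744-5p, fell by 0.71 (SE 0.10).

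No miRNA of 1908 rose in OFT-RV by limma, and 182 had an unadjusted p under 0.05. The arrays of the 2 genotypes did not overlap for any of the 7, which chance gives 10% of unselected miRNAs with 3 arrays against 3. The 7 were picked by p on the same arrays, so the separation adds no support. The count was 1 without any one of the 3 wild-type arrays, 3 without mutant replicate 2, 2 with an intensity trend and robust prior, and 38 when all miRNA arrays shared one fit. All of the 7 but miR-543-3p no longer passed in 3 or more of the 6 fits that left out 1 array, namely those without a wild-type array, and for some also those without mutant replicate 1, 2 or 3.

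Of 40 Dlk1-Dio3 miRNAs measured in OFT-RV 36 were lower (median -0.72), 3 fell and 37 did not pass, and adjusted over the list alone 19 fell, among them miR-667-3p at -1.54 (SE 0.23). The list passed with an adjusted p = 3.92e-18, and had an adjusted p = 0.0640 with an estimated correlation and 0.0108 by fry. All 7 miRNAs made without the Microprocessor were higher (median 0.39, adjusted p = 0.000484, and adjusted p = 0.104 with an estimated correlation), with 0.0186 by fry. Adjusted over the list alone 2 of these rose, the mirtron products miR-877-5p at 1.12 (SE 0.31) and miR-877-3p at 0.39 (SE 0.12), while miR-320-3p and miR-484, which come from capped transcripts, were at 0.40 (SE 0.15) and 0.36 (SE 0.18).

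Of 7 muscle miRNAs 6 were lower in OFT-RV (median -0.37, adjusted p = 0.0210, and adjusted p = 0.378 with an estimated correlation), with miR-1a-3p at -1.27 (SE 0.54), miR-133b-3p at -0.61 (SE 0.25) and miR-133a-3p at -0.47 (SE 0.20). Of 13 miRNAs of the miR-17-92 and paralogous clusters 11 were lower (median -0.38, adjusted p = 0.0210, and adjusted p = 0.623 with an estimated correlation), with miR-92a-3p at -0.31 (SE 0.12). All 4 of the miR-130 and miR-301 family were lower (median -0.43, adjusted p = 0.00941, and adjusted p = 0.378 with an estimated correlation), with miR-301a-3p at -0.76 (SE 0.22) passing over the list alone. Both measured miRNAs of the miR-143 and miR-145 locus were lower (median -0.52, adjusted p = 0.0308, and adjusted p = 0.378 with an estimated correlation), with miR-145a-5p at -0.65 (SE 0.13) passing over the list alone. Centred on small RNAs outside miRBase, the muscle, miR-17-92, miR-130 and miR-301, and miR-143 and miR-145 lists no longer passed, with adjusted p of 0.114, 0.226, 0.0698 and 0.140, and with dim probe sets left out miR-143 and miR-145 had 0.0968.

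These 4 calls depended on single arrays of OFT-RV. Without mutant replicate 3 the miR-17-92 list had a median of -0.015 (adjusted p = 0.896) and miR-143 and miR-145 one of -0.25 (0.178), with miR-143-3p at 0.019. Without wild-type replicate 1 all 4 lists no longer passed (0.0751, 0.119, 0.0537 and 0.0898 in the order above), and without wild-type replicate 2 muscle (0.0770) and miR-143 and miR-145 (0.0770) did not. Among muscle miRNAs miR-1a-3p was at -0.78 without wild-type replicate 2. The Dlk1-Dio3 and Microprocessor-independent lists passed in each of the 6 fits that left out 1 array.

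The other 8 miRNA lists did not pass in OFT-RV. Of 9 let-7 family miRNAs 7 were lower (0.170), with let-7e-5p at -1.09 (SE 0.41). Of 6 of the miR-15-16 family 5 were lower (0.0774), with miR-15b-5p at -0.39 (SE 0.10) passing over the list alone. Of 6 miRNAs of the miR-199 and miR-214 locus 5 were lower (0.463), miR-199a-3p and miR-199b-3p sharing one value of -0.67 (SE 0.51). Of 11 of the miR-302, miR-367 and miR-290 clusters 7 were higher (0.339), the median of 0.10 turning to -0.014 with arrays centred on small RNAs outside miRBase, and of 7 epithelial miRNAs 6 were lower (0.686), with miR-205-5p at 0.31 (SE 0.15). Of 4 erythroid miRNAs 2 were higher (0.618, median 0.016), with miR-486-5p at 0.37 (SE 0.20). Both measured endothelial miRNAs were higher (0.462), and of 6 neural miRNAs 3 were lower (0.772), with a median of -0.013, a mean of 0.0075 and an upward test. That centring also turned the erythroid median to -0.10. On leaving out 1 array, let-7 passed without mutant replicate 2 (adjusted p = 0.0426), miR-302 without mutant replicate 3 (0.0381), miR-199 and miR-214 without mutant replicate 1 (0.0487), and miR-15 and miR-16 without wild-type replicate 3 (0.0153) or mutant replicate 1 (0.0487).

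Between tissues, 3 mature miRNAs changed differently, all lower in OFT-RV relative to aSHF. They were miR-378b at -2.24 (SE 0.26, adjusted p = 0.00126), miR-543-3p at -1.73 (SE 0.27, adjusted p = 0.0200) and miR-134-5p at -1.19 (SE 0.20, adjusted p = 0.0286). At an unadjusted p under 0.05 limma gave 115 miRNAs. In aSHF all 7 miRNAs that fell in OFT-RV were lower by sign, but none passed. Their aSHF changes ran from -0.014 (SE 0.15) for miR-378b to -0.48 (SE 0.34) for miR-378a-3p. Only miR-134-5p, at -0.34 (SE 0.13), had an unadjusted p under 0.05 there by limma. On the aSHF arrays miR-378b was at 1.04 ± 0.27 (SD, n = 4) in wild-type pools. That is below the 2.74 that is the 95th percentile of background probe sets there. The count was 1 without aSHF wild-type replicate 1 or any one of the OFT-RV wild-type arrays, 8 without OFT-RV mutant replicate 2, 11 after a second quantile normalization and 1 with an intensity trend. With a replicate block it was 1 too. Leaving out aSHF wild-type replicate 1 or any OFT-RV wild-type array ended the calls of miR-543-3p and miR-134-5p, and leaving out aSHF wild-type replicates 2 or 4, aSHF mutant replicates 1, 3 or 4 or OFT-RV mutant replicate 3 ended that of miR-134-5p.

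Whether a mature miRNA was lower where its gene was higher was compared at loci with a mature miRNA above a mean log2 value of 3 in the tissue. A mature miRNA of several loci was counted only at the locus whose gene had the highest change there. In OFT-RV the brightest mature miRNA had a median change of -0.48 at 36 loci whose gene passed, where 34 were lower, and of -0.50 at the other 39, where 28 were lower. Over the 74 miRNAs of these loci the median was -0.49, and -0.23 without mutant replicate 3. Across the 75 loci Pearson r was 0.016 (permutation p = 0.889) and Spearman rho -0.11 (permutation p = 0.342). In aSHF the medians were -0.18 at 28 loci, where 26 were lower, and -0.14 at 93 loci, where 71 were lower. There r was -0.11 (permutation p = 0.230) and rho -0.20 (permutation p = 0.0292) across 121 loci. Adjusted over these 4 correlations the lowest p was 0.117 and the others were 0.456, 0.456 and 0.889. Loci of one cluster are not independent replicates.

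**Figure D4:**
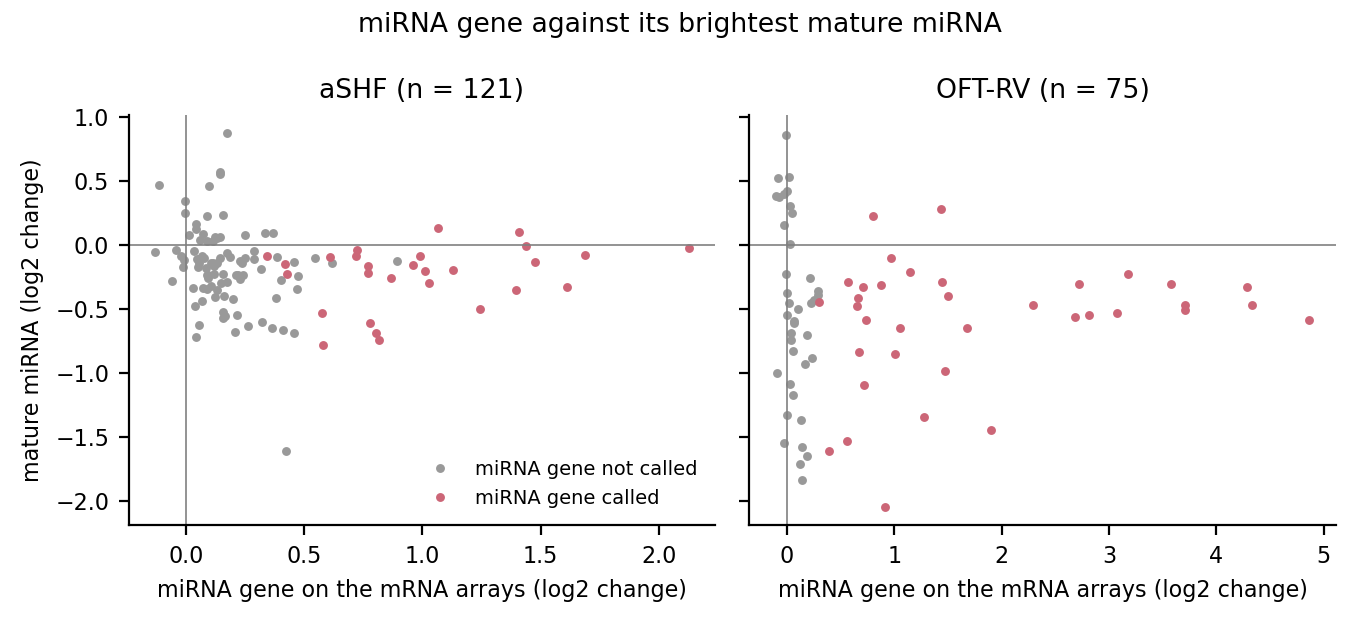
Change (log2) of each miRNA gene on the mRNA arrays (horizontal axis) and of its brightest mature miRNA on the miRNA arrays (vertical axis) at 121 loci in aSHF (left) and 75 in OFT-RV (right), in red where the gene passed. In OFT-RV 34 of 36 red points lie below 0 on the vertical axis.

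Few protein-coding genes that span miRNA genes changed with them. In OFT-RV 21 miRNA genes that passed (median 0.97) lay within 15 such genes, whose median change was 0.031, within a range of -0.12 to 1.09. Mib1, which spans Mir133a-1 and Mir1a-2, was at 0.031 and Mcm7, which spans Mir106b, at 0.077, both chosen after their values were seen. Of these 15 genes 2 passed, 2610318N02Rik, which spans Mir130b (0.30) and Mir301b (1.96), and Nr6a1, which spans Mir181a-2 (0.32). In aSHF 8 miRNA genes that passed (median 0.88) lay within 4 genes with a median of 0.036, and none of the 4 passed. Which strand the spanning genes lie on was not part of the comparison.

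In the authors' deposited tables, 18 genes had an adjusted p under 0.05 in aSHF, all higher in mutants and 17 of them miRNA genes. In OFT-RV 62 did, 61 higher and 1 lower, and 54 were miRNA genes. Of 3163 mouse probe sets on the miRNA arrays the authors' tables gave 0 in aSHF and 9 in OFT-RV, all lower.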

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

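The tests of a scale factor, of a floor, of recombined cells, of 1 mutant array, of lower transcription at Dlk1-Dio3, of centring on small RNAs outside miRBase and of all other divisions of the arrays were chosen only after the result was seen. The tests on sets matched by level were set down after the patterns were seen but before their own values were.

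Between tissues, the change of miRNA genes differed by interaction, with values for OFT-RV minus aSHF. The differences were 4.12 for Mir19a, 4.09 for Mir30d, 3.97 for Mir18, 3.48 for Mir133a-2, 2.72 for Mir1a-2, 2.65 for Mir20a, 2.61 for Mir30b, 2.501 for Mir322, 2.36 for Mir133a-1 and 2.31 for Mir181b-1. Tspan13 differed by -0.55 and Flywch2 by -0.35, and on the miRNA arrays miR-378b differed by -2.24, miR-543-3p by -1.73 and miR-134-5p by -1.19.

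Of 77 miRNA genes called in either tissue, 71 had the larger change in OFT-RV (median 1.19 against 0.47), which the choice of genes favours, since 75 were called there, while of all 321 miRNA genes 176 did (median difference 0.015) and 34 passed the test of the difference, all 34 larger in OFT-RV. With array values taken as linear, 38 of the 77 lay more than 3 standard errors from the fitted fraction of 0.27. This argues against a single scale factor between the tissues' arrays only where no floor acts. Likewise 45 of the 77 lay that far from one fitted fraction of the fold above 1. That argues against a larger share of recombined cells in OFT-RV as the only difference, again only without a floor. A floor on the aSHF arrays could itself scatter genes off one fraction. A floor of dim probe sets on the aSHF arrays cannot be told apart, since aSHF level and difference had a rank correlation of 0.0024 (bootstrap interval -0.23 to 0.24), but only 4 of the 34 miRNA genes that differed lay above the median aSHF level. A larger share of recombined cells as part of the difference may contribute and cannot be told apart either. Dgcr8 changed by -0.29 more in OFT-RV (limma, unadjusted p = 0.00157, adjusted p = 0.409 over all genes). An exact permutation p of 0.10 came from permuting genotype in both tissues. It therefore tests no change in either tissue and does not decide on the difference. A tissue difference in which miRNA genes are transcribed stays open, and a partial test of it by mature miRNAs (Fisher's exact test, p = 0.0508) decided nothing.

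All 7 Microprocessor-independent miRNAs were higher in OFT-RV mutants (median 0.39), on each of the 3 mutant arrays as list medians of 0.39, 0.43 and 0.33. Normalization to equal distributions could raise miRNAs that do not need Dgcr8. Against this, the list's median lay at percentile 99.99 of 10000 sets of small RNAs outside miRBase matched on level. The central range of those sets was -0.15 to 0.19. With arrays centred on those small RNAs the list's median was 0.27. Centring moves all miRNAs of an array alike, here by -0.12, so it argues only against a common shift of whole arrays. Mutant replicate 3 alone is argued against, since the median was 0.43 without it. Only 13 small RNAs outside miRBase were as bright as the brightest member, which limits the matched sets. With that limit both technical explanations tested are argued against, and a real rise of miRNAs that bypass the Microprocessor is a candidate explanation, found and tested on the same arrays. On the aSHF arrays the same list did not pass.

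Dlk1-Dio3 miRNAs were lower in OFT-RV mutants (median -0.72), and on each of the 3 mutant arrays the list's median was -0.67, -0.60 and -0.84. A fall that depends on level is argued against, since the median lay at percentile 0 of 10000 matched sets of mature miRNAs, the lowest of which was -0.49. Mutant replicate 3 alone is argued against by a median of -0.67 without that array. With arrays centred on small RNAs outside miRBase the median was -0.84, which argues against one shift of whole arrays. Since centring moves all miRNAs of an array alike, here by -0.12, it decides nothing else on normalization to equal distributions. Lower transcription cannot be told apart, since the 39 miRNA genes of the locus (median 0.67 on the mRNA arrays, with 23 that rose and 0 that fell) measure unprocessed transcripts, which build up when Dgcr8 is lost, while Meg3 of the same locus, chosen after its value was seen, was at 0.055 (SE 0.062). A loss of processing in cells where this locus is active may account for the fall too, as a hypothesis that these pools cannot test by cell type.

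In 11 of 190 groups of 4 arrays, 1 array stood apart from the other 3, where chance gives about 1 in 20 groups. Among genes, Mir136 was at 4.96 on aSHF wild-type replicate 1 against a mean of 5.13 on the others, Mir92-1 at 9.51 on aSHF mutant replicate 4 against 9.41, Mir30d at 6.14 on OFT-RV wild-type replicate 4 against 5.85, Mir133a-2 at 4.44 on OFT-RV wild-type replicate 2 against 4.80, and Tspan13 at 10.06 on OFT-RV mutant replicate 3 against 9.80. Among list means, branchiomeric muscle was at 7.70 on aSHF wild-type replicate 4 against 7.77 and at 7.74 on aSHF mutant replicate 1 against 7.84, and neural crest at 9.42 on aSHF wild-type replicate 4 against 9.56. On OFT-RV mutant replicate 4 the epicardium list was at 6.73 against 6.43 and the extracellular matrix list at 9.13 against 8.37. The list of miR-17 and miR-302 targets was at 9.19 on aSHF mutant replicate 4 against 9.17.

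Outside the genes tested, 14714 probe sets of the mRNA arrays were left, 14693 of them with no name here. In aSHF 3 of these passed, 1 rising and 2 falling, and in OFT-RV 6 passed, all 6 rising with a median of 1.29.

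Other divisions of the arrays argue against chance for the OFT-RV genes (93, highest other 0, only 1 of 35 divisions as large) and for the miRNA genes among them (75, highest other 0). As 1 of 35 is the smallest share possible, they do not firmly exclude it. For the aSHF miRNA lists the real division gave the most by a margin of 1 list (4, highest other 3). However, 0 of these lists passed with an estimated correlation and 1 by fry. As 1 of 35 is the smallest share possible here too, chance is not firmly excluded for these lists. By count alone chance is not excluded for the aSHF genes, where 2 of 35 divisions gave as many (37, highest other 1285), nor for the miRNA genes among them (36, highest other 40). Of the 37, however, 35 also rose on the OFT-RV arrays, where 0.16 were expected, which argues against a chance division of the aSHF arrays for these 35. That argument takes the tissues' arrays, and genes of a cluster, as independent. Across tissues, deviations of same-numbered mRNA arrays from their group mean had a mean r of 0.18 in wild-type and 0.15 in mutants. Other numbers had -0.059 and -0.051. Chance is not excluded for the gene lists in aSHF, with 31 of 35 (1, highest other 10), or for those in OFT-RV, with 10 of 35 (5, highest other 8). The aSHF miRNA count was 0, so that all 35 divisions were as large by construction (highest other 0) and say nothing on chance. For the differences between tissues 5 of 100 divisions gave as many genes (44, highest other 2501) and 4 of 100 as many miRNA genes (34, highest other 76). These divisions were drawn from a larger number, so 4 and 5 cannot be told apart, and chance is not excluded by either count. They also shuffled genotype in both tissues, so they ask about no change in either tissue. On the difference itself these counts cannot decide. For miRNAs that differed, with 14 of 100, chance is not excluded (3, highest other 21), with the same limit. The 10 divisions of the OFT-RV miRNA arrays are too few (7 miRNAs, highest other 0, and 6 lists, highest other 5). The division with 2501 genes, whose cause was not found, held 0 of the 44, and its aSHF and OFT-RV parts called 0 genes each on their own. Its genes had a median difference of 0.31 in size. The division of aSHF arrays with 1285 genes set wild-type replicates 1, 3 and 4 and mutant replicate 1 against wild-type replicate 2 and mutant replicates 2, 3 and 4. It points to a structure of the arrays that overlaps genotype only in part, with 46.2% of variance on the first component. The median size of change was 0.23, and 0 of the 37 genotype genes were among them. On the side with more mutant arrays 85.9% of calls below the median level were higher, against 24.7% above it.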

How the results depend on the processing

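The main tests, lists, naming rule and the other alternatives were chosen before the data were examined. The exceptions, chosen only after the result was seen, were centring on small RNAs outside miRBase or on spike-ins, the background filter, the fit of all probe sets, for miRNA lists the estimated correlation, fry, block and filter, and for all lists leaving out arrays. No called result changed direction under any alternative run, except that the median of cell cycle genes in OFT-RV was -0.00062 without wild-type replicate 2, while the medians of some miRNA lists that had not passed changed sign when centred on small RNAs. Of 51 named calls, all kept their direction, and 16 were lost on leaving out 1 array, 8 with an intensity trend, 8 of 29 with all probe sets, 6 after a second quantile normalization and 5 with a replicate block. Unless a cause is given, the cause was not tested.

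For aSHF genes (37) the count was 16 at a change of at least 1, which is stricter by construction, 11 with dim probe sets left out, 60 with array weights, 18 with all probe sets in the fit, which adjusts over more tests, and 19 to 43 on leaving out single arrays (21 without wild-type replicate 3 and 19 without wild-type replicate 4). For OFT-RV genes (93) it was 47 at a change of at least 1, 46 with dim probe sets left out and 77 to 88 on leaving out arrays. For genes that differed between tissues (44) it was 26 at a change of at least 1, 21 with dim probe sets left out and 36 to 44 on leaving out arrays. Among the 10421 genes above the median of mean level over both tissues, with the calls of the full fits and not of the fits above, 18 were shared (35 among all). For aSHF miRNAs (0) it was 5 when centred on small RNAs outside miRBase and 0 to 2 on leaving out arrays (2 without mutant replicate 2). For OFT-RV miRNAs (7) it was 2 with an intensity trend, 38 with all arrays in one fit, of which 26.3% were higher, 11 when centred on small RNAs, and 1 to 9 on leaving out arrays (1 without any wild-type array, 3 without mutant replicate 2). For miRNAs that differed between tissues (3) it was 11 after a second quantile normalization, of which 36.4% were higher, 1 with an intensity trend, and 1 to 8 on leaving out arrays (1 without aSHF wild-type replicate 1 or any OFT-RV wild-type array, 8 without OFT-RV mutant replicate 2). Centring on small RNAs moved the median of all miRNAs by -0.20 in aSHF, by -0.12 in OFT-RV and by -0.18 between tissues.

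Gene lists called in aSHF (1) were 0 with an estimated correlation and 0 by fry, and in OFT-RV (5) they were 0 with an estimated correlation and 2 by fry. miRNA lists called in aSHF (4) were 0 with an estimated correlation, 1 by fry and 6 when centred on small RNAs, and in OFT-RV (6) 0 with an estimated correlation, 2 by fry and 2 when centred on small RNAs. On leaving out single arrays the lists called were 0 to 4 and 3 to 7 for genes, and 3 to 6 and 2 to 8 for miRNAs. With the replicate number as a block the counts in aSHF and OFT-RV were 51 and 95 genes, 0 and 9 miRNAs (11.1% of the latter higher), 2 and 7 gene lists, and 6 and 7 miRNA lists. Between tissues 53 genes and 1 miRNA differed with that block. The lists added were extracellular matrix in both tissues (0.0498 and 0.0374), machinery in OFT-RV (0.0406), let-7 and erythroid miRNAs in aSHF (0.0178 each) and miR-15 and miR-16 in OFT-RV (0.0314). Arrays that correlated best with their own number in the other genotype were 2, 2, 3 and 2 (mRNA in aSHF and OFT-RV, then miRNA). In the other tissue they were 2 and 3 (wild-type and mutant) on mRNA arrays and 1 each on miRNA arrays. Between genotypes the mean r of same-numbered arrays was 0.22, 0.11, 0.10 and 0.056, each above that of other numbers. Effects shared by replicate number are therefore not excluded, although the numbers are not stated to pair pools.

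Signal over background limits the miRNA arrays, since 15.8% of 1908 mature miRNAs in aSHF and 29.6% in OFT-RV lay above the 95th percentile of background probe sets in wild-type pools. Not run were the authors' own value tables, whose columns match no sample, single probe sets per gene, since each gene had 1, centring on mouse snoRNAs and a filter on plant and viral probe sets, since organisms are not named, and the seed match alternatives.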

Other observations

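Among the tests in this part, only that of whether mature miRNAs are made in a tissue was set down before its own value was seen, and all others were chosen only after the result was seen.

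Besides miRNA genes, 13 protein-coding genes rose in OFT-RV mutants (7 without mutant replicate 1 and 8 without wild-type replicate 3), all named here after their values were seen where not described before. Nmt2, an N-myristoyltransferase, rose by 0.52 (SE 0.08) and Acsl4, an acyl-CoA synthetase, by 0.46 (SE 0.06), and in aSHF they were at 0.0039 and 0.0052. Ak4, an adenylate kinase of mitochondria, rose by 0.43 (SE 0.07), Lcor, a nuclear receptor corepressor, by 0.42 (SE 0.07), and Ppp6c, a protein phosphatase, by 0.40 (SE 0.07). Ddx3x, Clcn3, Polr3g and Rhebl1 rose by 0.36 (SE 0.06), 0.30 (SE 0.04), 0.28 (SE 0.05) and 0.24 (SE 0.04).

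The 39 measured miRNA genes of the Dlk1-Dio3 locus were mostly higher in mutants of both tissues. In aSHF 11 rose and 36 were higher (median 0.40), and in OFT-RV 23 rose and 35 were higher. None of the 1255 precursor probe sets of the miRNA arrays passed in either tissue.

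A mature miRNA might be expected to be lower where its gene is higher, but across 75 loci in OFT-RV the rank correlation was -0.11, with a bootstrap interval of -0.34 to 0.15 that decides neither way.

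The brightest mature miRNAs of 74 miRNA genes were lower in OFT-RV mutants as a set (median -0.49, with 62 lower), by -0.22, -0.28 and -1.01 on the 3 mutant arrays. Mutant replicate 3 could account for part of this size, but not for all of it, since the median was -0.23 without that array, with 55 lower. In aSHF 97 of 120 were lower (median -0.16).

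Whether miRNA genes rise where their mature miRNA is normally made was tested with the aSHF calls. Of 17 genes that rose in OFT-RV and had a mature miRNA above background there alone, 4 rose in aSHF, against 29 of 55 with one above background in both tissues (Fisher's exact test, two-sided, p = 0.0508). The background limit was 2.74 in aSHF and 1.001 in OFT-RV, so that a miRNA of equal value in both can count as OFT-RV alone. The hypothesis may hold, but this test decides nothing.

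Higher transcription of the genes that span miRNA genes could raise the miRNA genes within them. In OFT-RV the median change of the spanning genes was 0.031, where the miRNA genes within them had a median of 0.97. Strand was not part of the comparison, and a gene on the opposite strand does not measure transcription through the miRNA gene. The values therefore argue against this explanation only for miRNA genes on the strand of their spanning gene, and how many these are was not determined. Of the 15 spanning genes 2 rose themselves, so for the miRNA genes within these 2 the explanation stays open.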
